A study of Mus musculus with 18 samples.

How the data were processed

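Gene expression was measured by RNA sequencing in 18 libraries from microdissected kidney tissue of male C57BL/6 mice in which Pkd1 had been inactivated in kidney epithelium by an inducible Cre. The libraries came from 3 kidneys and 3 region types: non-cystic regions, cystic regions with low F4/80 signal and cystic regions with high F4/80 signal. F4/80 is a macrophage surface protein encoded by Adgre1. Each kidney and region type had 2 libraries, labelled as biological replicates 1 and 2. The labels number kidneys and do not say whether they came from separate mice. Kidneys 1 and 3 share a labelled age of 269 and kidney 2 has 297, with no unit. Per the labels, the tissue was frozen, RNA was taken up in TRI reagent and libraries were made with a low-input kit that does not mark the strand, so counts of genes that overlap a gene on the other strand are uncertain. This holds for 16 of the 108 genes named here, among them Pkd1, Egf, Umod, Vcam1, Il34, Psmb8, Notum, Bicc1 and Atp6v1c2, and 4 (Col3a1, Cyp2d12, mt-Co3 and Slpi) overlap an exon on the same strand. The labels give no sequencing batch.

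The deposited values are raw counts per gene and library, with no normalization by the authors. The submitters' processing notes name the mouse assembly mm10 (GRCm38), FastQC 0.11.9, fastp 0.20.1 and HTSeq 0.11.0 without stating their roles. The aligner, the annotation release and the strand setting are not given in the sources used here. The table held 32285 genes, of which 4845 had no count in any library, and 127 identifiers without a symbol in the reference annotation, which held 0.00874% of the counts, were kept in the fits but not named. Library totals ran from 5366651 to 9188813 counts. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

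The following choices were made before the data were examined. Counts of the 2 libraries of a kidney and region type were summed, which gave 9 sums, because these libraries share a kidney. The sums were fitted in R 4.3.3 with edgeR 4.0.16 (trimmed mean of M values normalization, filterByExpr by region type, robust quasi-likelihood fit and test), with all 3 region types and the kidney as a block in 1 model that left 4 residual degrees of freedom. The filter left 16034 genes, which held 99.8% of the counts. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The comparisons were: F4/80-low cystic against non-cystic, F4/80-high cystic against non-cystic, and F4/80-high against F4/80-low cystic. The kidney is the unit of replication, and the block takes out differences in level between kidneys. The p-values set the region differences against how unevenly they repeat over the 3 kidneys. That spread was pooled over the 3 region types and moderated across genes.

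Gene lists, 33 with 541 distinct genes, were written for cell types, matrix, injury, secreted factors, metabolism, signalling targets and RNA quality. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation and with fry. Beside a list that passed with the preset correlation, the text gives the adjusted p with the estimated correlation, by which no list passed. Where neither that nor fry is named, a list's adjusted p is the one with the preset correlation. For each list the calls over all tested genes and the calls adjusted over the list alone were counted. Genes were named by rule: for each comparison the 8 largest higher and 8 largest lower fold changes among called genes with a mean log2 CPM of at least 3 and the same direction in all 3 kidneys, without predicted genes, immunoglobulin segments and unnamed identifiers; up to 4 genes per list with the smallest p; and Pkd1, Pkd2, Adgre1 and Cdh16. The text names part of the list genes that this rule allows, and that part was picked after the values were seen. Slpi, Lrg1, Sprr1a and Mymx lie outside the rule and were chosen after their values were seen.

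Fold changes are on the log2 scale and stand with a standard error (SE) from the fit over 3 kidneys. This SE was worked back from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. It may understate the error of genes with few counts. CPM values are means over 3 kidneys with the standard deviation (SD). A fold against a group with 1 to 3 counts is given as a ratio with its exact 95% counting interval, and a group with 0 counts was set to a floor of 3 counts over the group.

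The alternatives were 3 other scalings (size factors of DESeq2 1.42.0, upper quartile and total counts), no filter and a stricter filter (at least 50 counts in 3 or more sums), the DESeq2 Wald test, the 18 libraries as separate samples with the kidney as block, as random effect (limma voom) or without it, the 9 sums without the block, the 2 compared region types alone, the libraries of 1 replicate label alone, and each kidney and each library left out in turn. List counts without 1 doubted library (F4/80-low cystic, kidney 2, replicate 2), without each kidney and under the other scalings were added after seeing the data. The agreement of both cystic comparisons was set against 20 simulations of unchanged groups with shared controls and against fits that used separate non-cystic libraries for each. The fit was tested on simulated data with 200 changed genes. It recovered 73, 72 and 65% of 4-fold changes and 17, 21 and 13% of 2-fold changes in the 3 comparisons, and 2.17, 8.82 and 11.4% of its calls there were false. Each comparison had 1 simulation, in which all other genes were unchanged. In the data 39.2 and 24.3% of genes were called for F4/80-high against non-cystic and against F4/80-low regions. The simulated rates do not carry over to so many changes.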

Results

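The 18 libraries comprised 6 from non-cystic regions, 6 from F4/80-low cystic regions and 6 from F4/80-high cystic regions, each set from the same 3 kidneys. Total counts per library were 5366651 to 9002054 in non-cystic, 7186518 to 9188813 in F4/80-low and 5841975 to 8662288 in F4/80-high regions. The stated purpose of the study was to find factors by which cells signal to their neighbours around early cysts. The first principal component held 51.7% of the variance and ranged from -97.7 to -52.8 in non-cystic, from -53.0 to 7.90 in F4/80-low and from 59.1 to 140.9 in F4/80-high libraries. Mitochondrially encoded genes took 12.4% ± 1.75 (SD, n = 3 kidneys) of the counts in non-cystic, 9.15% ± 0.997 in F4/80-low and 2.75% ± 0.898 in F4/80-high regions. Spp1, which encodes the secreted protein osteopontin, took 0.0433 to 0.332%, 0.241 to 8.90% and 6.41 to 14.1% of a library's counts in the same order. The nuclear RNA Malat1 took 4.26 to 6.48%, 4.63 to 8.42% and 6.59 to 9.59%, and 17070 to 19594, 17804 to 19458 and 20033 to 20969 genes were detected.

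**Figure D1:**
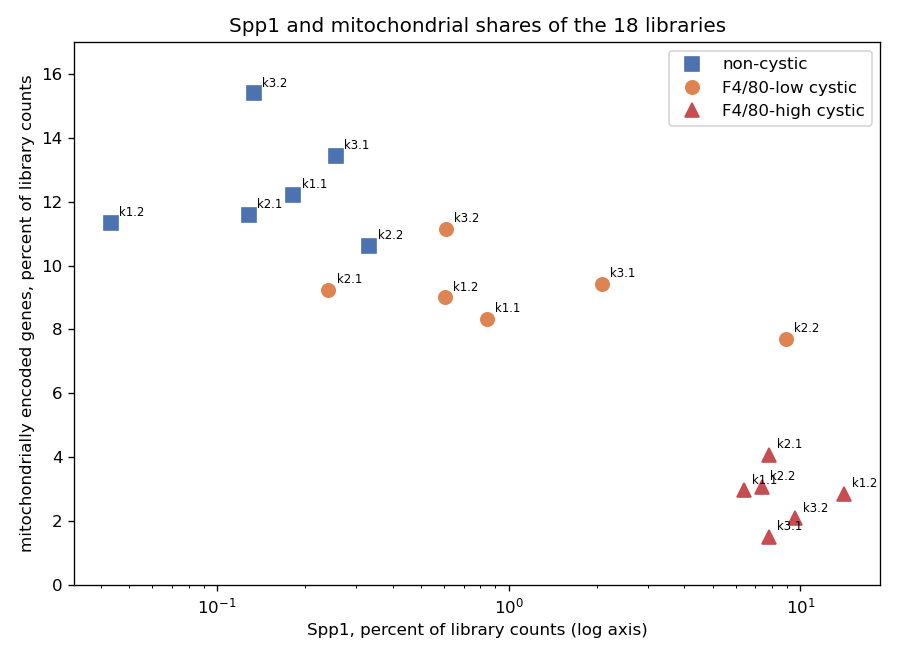
Percent of library counts from Spp1 (log axis) against percent from mitochondrially encoded genes, 1 point per library, labelled by kidney and replicate, with shapes for the 3 region types. Replicate 2 of F4/80-low kidney 2 had 8.90% Spp1, within the 6.41 to 14.1% of the F4/80-high libraries, while its mitochondrial share lay above all of theirs.

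Pkd1 (chromosome 17, 24549834 to 24596508), the deleted gene, had 24 to 141 counts in every library. Its level was 6.31 ± 1.32 CPM (SD, n = 3) in non-cystic, 7.16 ± 2.01 in F4/80-low and 9.50 ± 2.88 in F4/80-high regions. Every library came from a Pkd1 knockout and a count per gene also covers exons outside the deleted part, so this level checks neither genotype nor labels. Adgre1 (chromosome 17, 57358691 to 57483527), which encodes F4/80, had 2.56 ± 0.962 CPM in non-cystic, 6.55 ± 1.65 in F4/80-low and 53.9 ± 14.9 in F4/80-high regions. The regions were chosen on F4/80 signal, so this order is a check of the dissection and not a finding. The macrophage list holds Adgre1, and its rise in F4/80-high regions is a check of the same kind. The Adgre1 log2 fold change was 4.42 ± 0.31 for F4/80-high against non-cystic (adjusted p = 2.604e-05) and 3.06 ± 0.29 for F4/80-high against F4/80-low (adjusted p = 0.000834), and 1.36 ± 0.30 for F4/80-low against non-cystic, which did not pass (adjusted p = 0.0647).

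The comparison of F4/80-low cystic with non-cystic regions asked what differed around cysts with few macrophages. The higher genes included 8 of 8 MHC class II, 11 of 23 matrix, 8 of 20 tubular injury, 8 of 29 chemokine and cytokine and 6 of 14 complement genes, and no list passed as a set with an estimated correlation. Krt20 (ENSMUSG00000035775, chromosome 11, 99428403 to 99438150), a keratin, had 31.4 ± 16.0 CPM in F4/80-low and 0.111 ± 0.0965 CPM in non-cystic regions (SD, n = 3), a log2 fold change of 8.07 ± 0.52 (adjusted p = 0.000301). Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), the kidney injury molecule KIM-1, had 198.3 ± 143.8 against 1.11 ± 1.22 CPM, a log2 fold change of 7.38 ± 0.97 (adjusted p = 0.0223). C3, the central complement protein, rose by 4.39 ± 0.26 (adjusted p = 0.000105), from 6.13 ± 0.681 to 129 ± 18.8 CPM. Ccl2, a monocyte attractant, rose by 4.17 ± 0.31 (adjusted p = 0.000421).

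In all, 242 of 16034 genes were higher and 4 were lower in F4/80-low than in non-cystic regions, each in the same direction in 3 of 3 kidneys. Of these, 238 higher and 3 lower genes differed by more than 2-fold. The other large increases were Serpina10 (6.93 ± 0.65), Ubd (6.59 ± 0.47), the protease inhibitor Timp1 (6.28 ± 0.72), Ltbp2 (4.95 ± 0.51) and the chemokine Ccl12 (4.84 ± 0.70). Spaca7 had 161 counts against 3, a ratio of 47.0 with a 95% interval of 15.8 to 230.3. The 4 lower genes were Mymx (-2.69 ± 0.48), the proton pump subunit gene Atp6v1c2 (-2.35 ± 0.44), the protease inhibitor Slpi (-1.70 ± 0.31) and the transcription factor gene Etv1 (-0.87 ± 0.17). Atp6v1c2, Slpi and Etv1 lost their calls with total counts (adjusted p 0.0832 to 0.239). Over all 34 alternatives the call was lost in 17 for Etv1, 16 for Atp6v1c2, 13 for Slpi and 8 for Mymx. Pkd1 (0.20 ± 0.33, adjusted p = 0.903), Pkd2 (-0.15 ± 0.15, adjusted p = 0.826) and the kidney cadherin gene Cdh16 (-0.10 ± 0.24, adjusted p = 0.937) did not pass.

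Among the fixed lists, all 8 MHC class II genes rose, also when adjusted over the list alone, with a median of 1.95 (adjusted p = 0.0635 with an estimated correlation). H2-DMb2 rose by 3.14 ± 0.25 and H2-Ab1 by 2.49 ± 0.35. Of 24 macrophage genes, 13 rose and 11 were not called (23 higher when adjusted over the list alone), with a median of 1.78 (adjusted p = 0.123 with an estimated correlation). These included Cd14 (2.56 ± 0.26), Ms4a7 (2.07 ± 0.23) and Aif1 (2.03 ± 0.25). Of 9 monocyte genes, 2 rose, Ccr2 (1.76 ± 0.18) and Plac8 (1.78 ± 0.20), and 3 did when adjusted over the list alone (median 0.80, adjusted p = 0.190 with an estimated correlation). Of 23 fibroblast and matrix genes, 11 rose, with 21 adjusted over the list alone and a median of 1.90 (adjusted p = 0.123 with an estimated correlation); the collagen genes Col3a1 and Col1a1 rose by 3.56 ± 0.31 and 3.00 ± 0.31. Of 20 tubular injury genes, 8 rose, with 13 adjusted over the list alone and a median of 1.28 (adjusted p = 0.0698 with an estimated correlation). These included the adhesion molecule gene Vcam1 (3.89 ± 0.31), the transcription factor gene Sox9 (3.62 ± 0.44) and Cd44 (2.35 ± 0.28).

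Among secreted factors, 8 of 29 chemokine and cytokine genes rose, with 20 adjusted over the list alone and a median of 2.05 (adjusted p = 0.0675 with an estimated correlation). Besides Ccl2 these included Ccl9 (2.49 ± 0.37) and Il34 (1.43 ± 0.21), a ligand of the macrophage receptor Csf1r. Cxcl5 and Cxcl2 had 0 counts in non-cystic regions, and the list's median was the same with both at their bound. Of 14 complement genes, 6 rose, with 10 adjusted over the list alone and a median of 1.37 (adjusted p = 0.0532 with an estimated correlation). These included C4b (2.00 ± 0.21). Of 22 interferon response genes, 6 rose, with 19 adjusted over the list alone (median 1.55, adjusted p = 0.199 with an estimated correlation). These included Gbp2 (2.62 ± 0.39) and the immunoproteasome gene Psmb8 (1.72 ± 0.23). Of 36 growth factor genes, 1 rose and 3 did when adjusted over the list alone (median 0.60, adjusted p = 0.330 with an estimated correlation). Of 11 immediate early and heat shock genes, 3 rose, also over the list alone (adjusted p = 0.332 with an estimated correlation). Fos stood at 1.95 ± 0.34 and Jun at 1.70 ± 0.30; this list responds to handling of tissue as well.

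Of 26 proliferation genes, 2 rose, with 4 adjusted over the list alone (median 1.08, adjusted p = 0.274 with an estimated correlation); Mcm5 rose by 1.79 ± 0.35. In the YAP target list 1 of 10 genes rose, also over the list alone: Axl, by 1.25 ± 0.22 (adjusted p = 0.556 with an estimated correlation for the list). The proximal tubule (25 genes, median -0.34), oxidative phosphorylation (55, -0.21), fatty acid oxidation (21, -0.12) and mitochondrially encoded (13, -0.57) lists had 0 calls in edgeR, also over the list alone. At an unadjusted p below 0.05 they had 2, 0, 2 and 2 lower genes, and with the DESeq2 Wald test 2, 0, 0 and 0. Their adjusted p was 0.657, 0.657, 0.657 and 0.446 with an estimated correlation.

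The 10 distal convoluted and connecting tubule genes had a median of -1.91 and the 10 intercalated cell genes one of -1.93, with 0 calls each in edgeR. Lower genes numbered 2 and 8 when adjusted over the list alone, 5 and 8 at an unadjusted p below 0.05, and 2 and 7 with DESeq2 (adjusted p = 0.220 and 0.222 with an estimated correlation). Pvalb had a log2 fold change of -2.16 ± 0.42 (adjusted p = 0.0590) and Slc4a1, the anion exchanger gene of intercalated cells, one of -2.35 ± 0.57 (adjusted p = 0.0958).

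In 4 further lists 1 gene each was higher: alternative macrophage activation (of 9), basement membrane (of 17), smooth muscle and pericytes (of 12) and adipocytes (of 2). Over the list alone 2, 5, 2 and 1 were higher, and the adjusted p was 0.274, 0.519, 0.506 and 0.330 with an estimated correlation. In edgeR 0 genes were called of 17 lymphocyte (3 higher at an unadjusted p below 0.05, 1 with DESeq2), 14 endothelial (3 and 0) and 8 Wnt target genes (1 and 0), with 1, 0 and 0 over the list alone. The adjusted p was 0.363 for lymphocytes and 0.601 for endothelium with an estimated correlation. There were also 0 calls of 5 neutrophil (1 lower over the list alone, unadjusted and with DESeq2), 8 thick ascending limb (1 higher and 1 lower unadjusted, 0 with DESeq2) and 10 principal cell genes (0 unadjusted, 1 higher and 2 lower with DESeq2). The adjusted p was 0.519 for neutrophils and 0.556 for principal cells with an estimated correlation. The glycolysis list (17 genes) had 0 calls, 1 higher gene over the list alone, 2 higher and 1 lower unadjusted and 1 higher with DESeq2, and its median (-0.12, but 0.02 with total counts) and mean (0.14) differed in sign. The 10 podocyte, 20 polycystic and ciliary, 5 erythrocyte and 1 urothelial genes had 0 calls in edgeR, over the list alone, unadjusted and with DESeq2. For podocytes this does not mean equal levels: the list's median was 2.88, 1.42 and -2.96 in kidneys 1, 2 and 3.

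With the preset correlation 26 of 33 lists passed in this comparison, 18 higher and 8 lower. With an estimated correlation 0 passed (8 at an unadjusted p below 0.05), and with fry 8. The lists that passed fry were macrophages, monocytes, MHC class II, matrix, tubular injury, chemokines and cytokines, complement and interferon response. The counts rested in large part on replicate 2 of F4/80-low kidney 2, the library with 8.90% Spp1. Without it 31 genes were higher and 0 lower in edgeR, 30 of them among the 246. The lists then had 3 macrophage, 1 MHC class II, 5 matrix and 3 injury calls at medians of 1.53, 1.67, 1.73 and 1.14. Chemokine, complement, interferon and immediate early lists had 0 calls at medians of 1.80, 1.24, 0.80 and 0.56. Of the 37 called genes named for this comparison, 26 lost their call without that library (adjusted p 0.0747 to 0.462), with the sign kept in all 37. Havcr1, C3 and Ccl2 were among the 26, while Krt20 kept its call. With the kidney as a random effect 22 of the 37 lost it (adjusted p 0.0528 to 0.790). There were 22 higher genes without kidney 1, 76 without replicate 1 of F4/80-low kidney 3, and 129 without replicate 1 of non-cystic kidney 2.

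The comparison of F4/80-high cystic with non-cystic regions asked what differed where macrophages were dense. Among the higher genes were 23 of 24 macrophage, 23 of 23 matrix, 16 of 20 tubular injury and 23 of 29 chemokine and cytokine genes. The macrophage count checks the choice of regions by F4/80 and is not a finding. The lower genes included 23 of 25 proximal tubule and 55 of 55 oxidative phosphorylation genes, and no list passed as a set with an estimated correlation. Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799), a monocyte attractant, had 206.3 ± 144.9 CPM against 0.203 ± 0.195 CPM (SD, n = 3), a log2 fold change of 10.20 ± 1.46 (adjusted p = 0.00318). Pvalb (ENSMUSG00000005716, chromosome 15, 78191114 to 78206400), a calcium-binding protein of the distal convoluted tubule, had 0.116 ± 0.20 CPM against 67.9 ± 28.6 CPM, a log2 fold change of -9.41 ± 0.68 (adjusted p = 0.000102). Col3a1 rose from 7.25 ± 1.27 to 278.3 ± 90.2 CPM (5.26 ± 0.33, adjusted p = 1.595e-05), and the growth factor precursor gene Egf fell from 332.5 ± 116.3 to 10.7 ± 9.12 CPM (-5.15 ± 0.65, adjusted p = 0.000972).

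Here 3156 genes were higher and 3133 lower, and 6268 of these 6289 went the same way in 3 of 3 kidneys. Differences over 4-fold were found for 1523 higher and 694 lower genes. Further large increases were Krt20 (9.14 ± 0.52), the chemokine gene Ccl7 (8.75 ± 0.96), Havcr1 (8.53 ± 1.01), Timp1 (8.44 ± 0.72) and Serpina10 (8.36 ± 0.66). Fcrls had 2930 counts against 2, a ratio of 967.8 (95% interval 267.7 to 7995), and Serpina1f 920 against 1, a ratio of 607.8 (108.8 to 24030). The largest decreases after Pvalb were Cyp2d12 (-6.12 ± 1.13), Ces1g (-5.72 ± 0.75), Rdh16f2 (-5.44 ± 1.12), Hpd (-5.12 ± 0.66), the organic anion transporter gene Slc22a8 (-5.03 ± 0.98) and the brush border protease gene Mep1b (-4.97 ± 1.56, adjusted p = 0.0493). Serpina1f, Ces1g, Cyp2d12 and Rdh16f2 belong to families of similar genes, whose reads are hard to tell apart. Pkd2 fell by 0.58 ± 0.15 (adjusted p = 0.0129) and was 0.03 when libraries were scaled by total counts; Pkd1 did not pass (0.58 ± 0.33, adjusted p = 0.184), and Cdh16 fell by 0.80 ± 0.24 (adjusted p = 0.0241), but by 0.19 with total counts (adjusted p = 0.425).

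Of the macrophage genes, 23 of 24 rose, also when adjusted over the list alone, with a median of 4.26 (adjusted p = 0.123 with an estimated correlation). These included Ms4a7 (4.81 ± 0.25) and Cd53 (3.94 ± 0.24). All 8 MHC class II genes rose, also over the list alone, with a median of 3.80 (adjusted p = 0.0815 with an estimated correlation). H2-DMb2 rose by 5.09 ± 0.26 and H2-Aa by 3.95 ± 0.34. Of 9 monocyte genes, 7 rose, also over the list alone (median 2.87, adjusted p = 0.123 with an estimated correlation). Ccr2 stood at 3.85 ± 0.19. Of 9 alternative activation genes, 6 rose and 8 did when adjusted over the list alone (median 2.40, adjusted p = 0.199 with an estimated correlation). Of 17 lymphocyte genes, 13 rose, also over the list alone (median 2.43, adjusted p = 0.199 with an estimated correlation). The T cell gene Cd3g rose by 3.53 ± 0.43, the cytotoxic cell gene Nkg7 by 3.03 ± 0.32 and the B cell gene Cd79b by 2.17 ± 0.23. The neutrophil list had 2 of 5 genes higher, also over the list alone (median 1.08), and its set test did not pass (adjusted p = 0.222).

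All 23 fibroblast and matrix genes rose, also over the list alone, with a median of 3.16 (adjusted p = 0.199 with an estimated correlation). These included Col1a1 (4.95 ± 0.33) and Mgp (4.11 ± 0.31). Of 12 smooth muscle and pericyte genes, 8 rose, also over the list alone (median 1.64, adjusted p = 0.540 with an estimated correlation). Acta2 rose by 2.88 ± 0.60. Of 17 basement membrane genes, 9 rose and 3 fell, or 11 and 4 adjusted over the list alone (median 0.94, adjusted p = 0.559 with an estimated correlation). Among 20 tubular injury genes, 16 rose, also over the list alone (median 2.99, adjusted p = 0.123 with an estimated correlation). Vcam1 rose by 5.55 ± 0.33, Sox9 by 5.18 ± 0.45 and Cd44 by 3.93 ± 0.28. The endothelial list had 1 higher gene, Pecam1 (0.70 ± 0.21), and 1 lower gene, Flt1 (-0.65 ± 0.20), with 0 over the list alone and a median of 0.40. The Flt1 call was lost with total counts (-0.02, adjusted p = 0.951) and upper quartile factors (-0.53, adjusted p = 0.0642), and the Pecam1 call without replicate 1 of F4/80-high kidney 3 (0.20, adjusted p = 0.550) and without the kidney block (0.65, adjusted p = 0.0565). The podocyte list (median 1.45) had 0 of 10 genes called in edgeR, also over the list alone, with 1 higher at an unadjusted p below 0.05 and 1 with DESeq2.

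Chemokine and cytokine genes numbered 23 higher and 2 lower of 29, or 24 and 2 adjusted over the list alone (median 2.87, adjusted p = 0.123 with an estimated correlation). Ccl2 stood at 6.18 ± 0.32 and Ccl6 at 4.97 ± 0.36. Growth factor genes numbered 18 higher and 4 lower of 36, or 19 and 5 adjusted over the list alone (median 1.17, adjusted p = 0.436 with an estimated correlation). The activin subunit gene Inhba (5.03 ± 0.67) and Igf1 (2.40 ± 0.24) rose, and Egf and Bmp7 (-1.51 ± 0.19) fell. Of 14 complement genes, 11 rose, with 11 higher and 1 lower adjusted over the list alone (median 3.25, adjusted p = 0.0577 with an estimated correlation). C3 rose by 5.61 ± 0.27 and the receptor gene C3ar1 by 4.88 ± 0.26. Of 22 interferon response genes, 17 rose and 20 did when adjusted over the list alone (median 2.16, adjusted p = 0.330 with an estimated correlation). Psmb8 rose by 3.19 ± 0.24. Of 26 proliferation genes, 19 rose and 1 fell, or 22 and 1 adjusted over the list alone (median 1.90, adjusted p = 0.344 with an estimated correlation). Ube2c rose by 2.33 ± 0.30, and the mitotic motor gene Kif11 fell (-3.49 ± 0.47, adjusted p = 0.00102).

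Of 25 proximal tubule genes, 23 fell and 24 did when adjusted over the list alone, with a median of -3.34 (adjusted p = 0.317 with an estimated correlation). These included Ass1 (-4.00 ± 0.50), Cyp4b1 (-3.84 ± 0.47) and the water channel gene Aqp1 (-2.49 ± 0.31). Of 8 thick ascending limb genes, 3 fell and 4 did over the list alone (median -0.85, adjusted p = 0.366 with an estimated correlation). These included the sodium transporter gene Slc12a1 (-2.07 ± 0.32), which lost its call without replicate 2 of non-cystic kidney 3 (-1.19, adjusted p = 0.564) and in all 3 fits of 18 libraries (adjusted p = 0.817 with the kidney as random effect). Of 10 distal convoluted and connecting tubule genes, 8 fell, also over the list alone (median -2.32, adjusted p = 0.316 with an estimated correlation). Klk1 fell by 3.73 ± 0.71 and Slc12a3 by 2.73 ± 0.57 on the log2 scale. Klk1 lost its call without replicate 1 of non-cystic kidney 1 (adjusted p = 0.0674) and Slc12a3 without replicate 1 of F4/80-low kidney 2 (adjusted p = 0.352), with values of -3.43 and -2.40. Of 10 intercalated cell genes, 6 fell and 9 did over the list alone (median -1.77, adjusted p = 0.540 with an estimated correlation). Slc4a1 stood at -2.99 ± 0.57. In the principal cell list 1 of 10 genes fell, also over the list alone: Aqp3, at -3.90 ± 0.80 (median -1.13, camera adjusted p = 0.0688).

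All 55 oxidative phosphorylation genes fell, also over the list alone, with a median of -1.46 (adjusted p = 0.413 with an estimated correlation). These included Uqcrfs1 (-1.93 ± 0.30) and Sdhc (-1.46 ± 0.23). The 13 mitochondrially encoded genes fell, also over the list alone, with a median of -2.995 (adjusted p = 0.233 with an estimated correlation). mt-Co3 fell by 3.74 ± 0.40 on the log2 scale. Of 21 fatty acid oxidation genes, 20 fell, also over the list alone (median -1.62, adjusted p = 0.317 with an estimated correlation). These included Ehhadh (-3.63 ± 0.39). In the glycolysis list 2 genes rose and 8 fell of 17, also over the list alone (median -0.65), and the set test did not pass (adjusted p = 0.0825): Hk2, a hexokinase gene, rose by 4.99 ± 0.75 and Pgk1 fell (-1.14 ± 0.21). All 5 erythrocyte genes fell, also over the list alone (median -2.22, adjusted p = 0.501 with an estimated correlation). Hbb-bs stood at -2.21 ± 0.59, but 0 were called without kidney 2.

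Of 20 polycystic disease and ciliary genes, 3 rose and 4 fell, also over the list alone, with a median of -0.07 that was 0.56 when scaled by total counts and 0.05 with upper quartile factors. Bicc1 (0.91 ± 0.20) and Kif3a (0.74 ± 0.16) rose, and Pkd2 and the transcription factor gene Glis3 (-0.71 ± 0.17) fell. With total counts Glis3 stood at -0.11 and lost its call (adjusted p = 0.680). Of 10 YAP target genes, 6 rose, also over the list alone (median 1.03, adjusted p = 0.538 with an estimated correlation). Axl rose by 2.71 ± 0.22. In the Wnt target list 2 rose and 2 fell of 8, also over the list alone: Nkd1 rose (2.71 ± 0.56), while Notum (-3.58 ± 0.52) and Sp5 (-2.27 ± 0.33) fell. The Wnt list's median (0.57) and mean (0.12) were positive where its set test pointed down without passing (adjusted p = 0.722). Of 11 immediate early and heat shock genes, 5 rose, also over the list alone (median 1.34, adjusted p = 0.455 with an estimated correlation). Egr1 rose by 2.82 ± 0.30 and Fos by 2.90 ± 0.34. In the adipocyte list 1 of 2 genes rose, also over the list alone, and the urothelial gene was not called in edgeR, with DESeq2 or unadjusted.

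With the preset correlation 24 of 33 lists passed, against 0 with an estimated correlation and 19 with fry. Those that passed fry included MHC class II and complement (fry adjusted p = 0.000615 each), macrophages (0.00224) and oxidative phosphorylation (0.0184). Scaling by total counts shifted the median of all genes by 0.61 and gave 6608 higher and 1463 lower genes, 81.9% higher in place of 50.2%, with 8 higher endothelial genes and 1 lower gene each in the intercalated cell and erythrocyte lists. Of the 73 called genes named for this comparison, 6 lost their call there: Mep1b, Glis3, Hbb-bs, Flt1, Pkd2 and Cdh16. At least 1 fit that left out a single library ended the call of Slc12a1, Klk1, Slc12a3, Mep1b, Pecam1, Flt1, Pkd2, Hbb-bs, Slpi, Lrg1 and Sprr1a. Without kidney 1 there were 1737 higher and 1622 lower genes, with 23 of 55 oxidative phosphorylation, 4 higher proliferation, 3 monocyte and 7 lymphocyte calls, and without kidney 2 there were 9 higher proliferation and 6 lymphocyte calls.

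**Figure D2:**
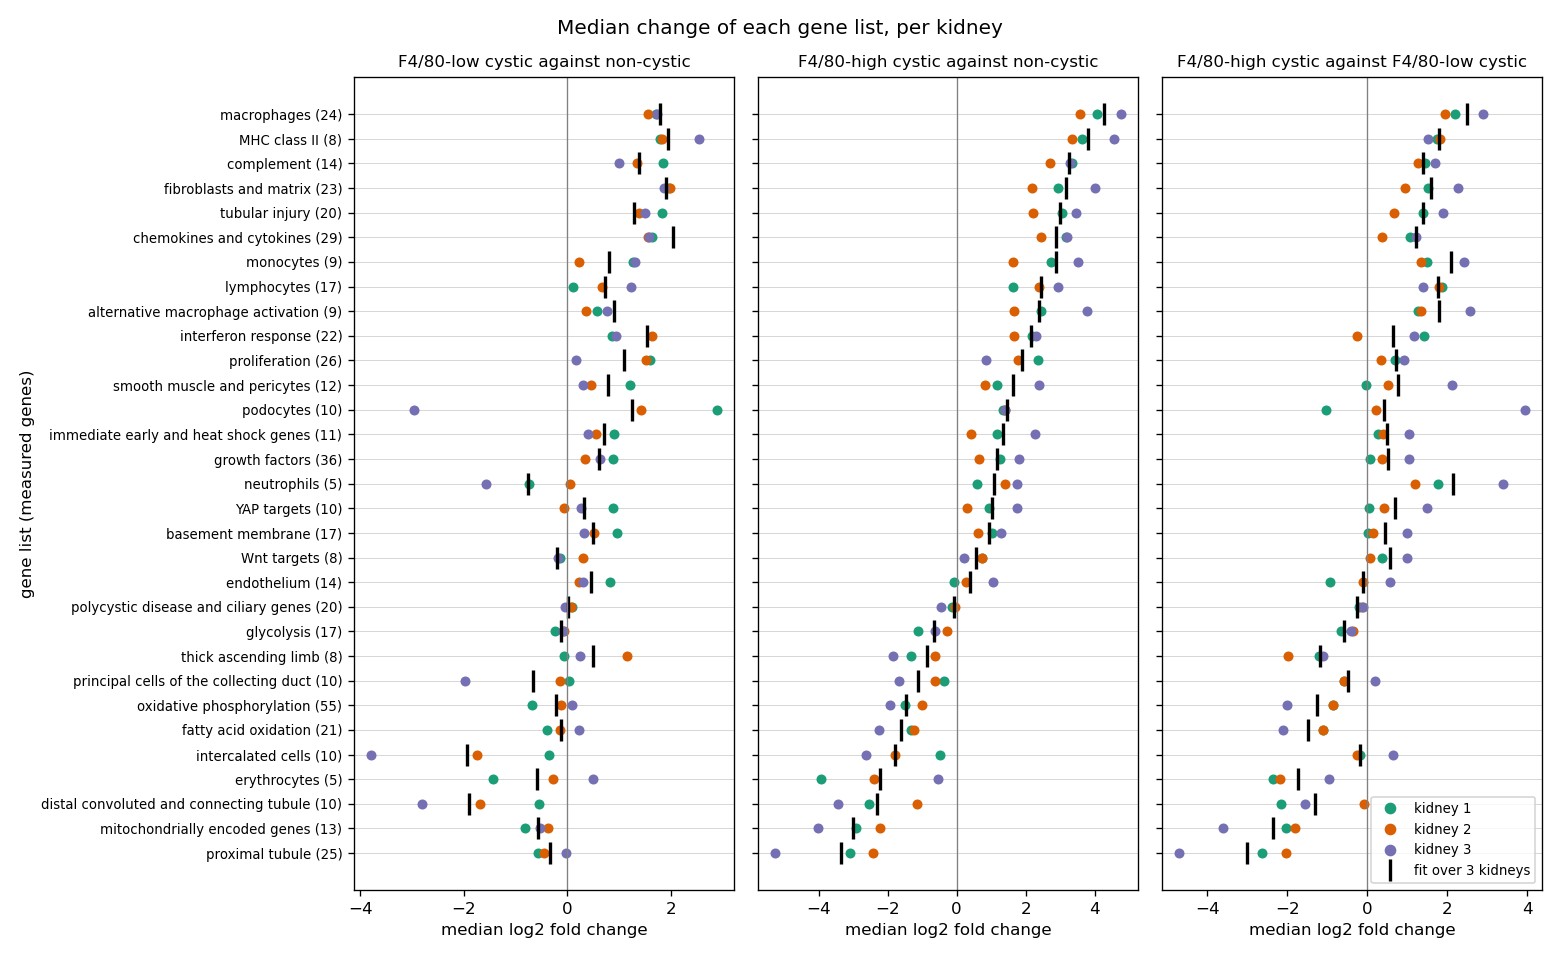
Median log2 fold change of each gene list with at least 5 measured genes in the 3 comparisons (separate axes), with a point per kidney from differences of log2 CPM and a bar for the fit over 3 kidneys, which can lie outside the points. For F4/80-high against non-cystic regions the bars run from -3.34 (proximal tubule) to 4.26 (macrophages), with all 3 kidneys on the same side of 0 in both lists.

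The comparison of F4/80-high with F4/80-low cystic regions asked what differed between cystic regions that differ in macrophage signal. In F4/80-high regions 22 of 24 macrophage and 16 of 23 matrix genes were higher. The macrophage count checks the choice of regions by F4/80 and is not a finding. Lower were 21 of 25 proximal tubule and 13 of 13 mitochondrially encoded genes, while no list passed as a set with an estimated correlation. Ccl8 had 206.3 ± 144.9 CPM against 3.63 ± 4.84 CPM (SD, n = 3), a log2 fold change of 6.30 ± 1.18 (adjusted p = 0.0148). The matrix protease gene Mmp7 had 55.0 ± 42.7 against 1.32 ± 1.98 CPM (5.99 ± 0.77, adjusted p = 0.00349). Pvalb fell from 21.0 ± 22.6 to 0.116 ± 0.20 CPM (-7.25 ± 0.68, adjusted p = 0.00123), and Hpd, an enzyme gene of tyrosine breakdown, from 30.7 ± 15.2 to 0.598 ± 0.362 CPM (-5.63 ± 0.67, adjusted p = 0.00253).

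Here 1649 genes were higher and 2246 lower, 3891 of the 3895 in the same direction in 3 of 3 kidneys, with 1266 and 1395 of them over 2-fold. Next among the increases stood Fcrls (4.89 ± 0.47), the peptide hormone gene Cck (4.78 ± 0.81), Rnase1 (4.76 ± 0.47), Kif1a (4.13 ± 0.42), Smoc2 (4.12 ± 0.68) and Thbs2 (4.08 ± 0.48). The decreases included Cyp4a14 (-6.26 ± 1.56), Slc22a7 (-5.93 ± 1.08), Mep1b (-5.84 ± 1.59), Rdh16f2 (-5.69 ± 1.16), Cyp2d12 (-5.62 ± 1.11) and Mogat2 (-5.24 ± 0.80). Pkd1 (0.38 ± 0.33, adjusted p = 0.428), Pkd2 (-0.43 ± 0.15, adjusted p = 0.0616) and Cdh16 (-0.69 ± 0.24, adjusted p = 0.0598) did not pass.

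Of the macrophage genes, 22 of 24 rose and 23 did when adjusted over the list alone (median 2.48, adjusted p = 0.149 with an estimated correlation). Mrc1, the mannose receptor gene, rose by 3.22 ± 0.33, Ms4a7 by 2.75 ± 0.22 and Cd53 by 2.61 ± 0.22. All 8 MHC class II genes rose, also over the list alone (median 1.80, adjusted p = 0.180 with an estimated correlation). H2-Aa rose by 2.26 ± 0.31. Of 9 monocyte genes, 4 rose and 8 did over the list alone (median 2.09, adjusted p = 0.196 with an estimated correlation). Ccr2 stood at 2.09 ± 0.17. Of 9 alternative activation genes, 3 rose and 4 did over the list alone (median 1.80, adjusted p = 0.199 with an estimated correlation). Of 17 lymphocyte genes, 6 rose and 9 did over the list alone (median 1.77, adjusted p = 0.199 with an estimated correlation). Cd3g rose by 2.41 ± 0.39 and Cd79b by 1.94 ± 0.23. Of 5 neutrophil genes, 4 rose, also over the list alone (median 2.15, adjusted p = 0.383 with an estimated correlation). S100a8 rose by 3.00 ± 0.40. Of 23 fibroblast and matrix genes, 16 rose and 18 did over the list alone (median 1.59, adjusted p = 0.330 with an estimated correlation). Mmp2 rose by 3.08 ± 0.41 and Col1a2 by 2.07 ± 0.29.

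Of 20 tubular injury genes, 11 rose and 13 did over the list alone (median 1.38, adjusted p = 0.220 with an estimated correlation). Vcam1 rose by 1.66 ± 0.27, Cd44 by 1.58 ± 0.25 and Clu by 1.56 ± 0.30. Chemokine and cytokine genes numbered 11 higher and 3 lower, or 12 and 4 over the list alone (median 1.21, adjusted p = 0.220 with an estimated correlation). Ccl6 stood at 3.25 ± 0.33, Ccl2 at 2.01 ± 0.25 and Il33 at 1.56 ± 0.21. Growth factor genes numbered 11 higher and 4 lower, or 12 and 5 over the list alone (median 0.53, adjusted p = 0.539 with an estimated correlation). Igf1 stood at 1.62 ± 0.23, Egf at -4.75 ± 0.63 and Bmp7 at -1.45 ± 0.19. Of 14 complement genes, 9 rose and 1 fell, or 10 and 2 over the list alone (median 1.41, adjusted p = 0.0878 with an estimated correlation). C3ar1 rose by 2.98 ± 0.23. Of 22 interferon response genes, 7 rose, or 7 and 1 lower over the list alone (median 0.65, adjusted p = 0.556 with an estimated correlation). Psmb8 rose by 1.47 ± 0.22. Of 26 proliferation genes, 3 rose and 1, Kif11, fell (-2.68 ± 0.46), or 1 and 1 over the list alone (median 0.72, adjusted p = 0.556 with an estimated correlation).

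Of 25 proximal tubule genes, 21 fell and 22 did over the list alone (median -3.003, adjusted p = 0.274 with an estimated correlation). Cyp4b1 stood at -3.36 ± 0.46, Ass1 at -3.29 ± 0.49 and Aqp1 at -2.47 ± 0.31. Of 8 thick ascending limb genes, 4 fell and 5 did over the list alone (median -1.17, adjusted p = 0.220 with an estimated correlation). Slc12a1 stood at -3.03 ± 0.33 and the uromodulin gene Umod at -1.99 ± 0.41. Of 10 distal convoluted and connecting tubule genes, 3 fell, also over the list alone (median -1.31, adjusted p = 0.501 with an estimated correlation). Of 55 oxidative phosphorylation genes, 53 fell and 55 did over the list alone (median -1.24, adjusted p = 0.383 with an estimated correlation). Uqcrfs1 stood at -1.81 ± 0.30. The 13 mitochondrially encoded genes fell, also over the list alone (median -2.35, adjusted p = 0.220 with an estimated correlation). mt-Co2 stood at -3.35 ± 0.42. Of 21 fatty acid oxidation genes, 18 fell and 20 did over the list alone (median -1.49, adjusted p = 0.274 with an estimated correlation). Ehhadh stood at -3.34 ± 0.39. Of 17 glycolysis genes, 7 fell, or 1 higher and 7 lower over the list alone (median -0.57, adjusted p = 0.492 with an estimated correlation).

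Smaller counts were found for the other lists. Of 10 YAP target genes, 2 rose, also over the list alone (adjusted p = 0.560 with an estimated correlation), and the Wnt target genes Notum (-3.47 ± 0.51) and Sp5 (-2.03 ± 0.33) fell, also over the list alone. The Wnt list's median (0.56) and mean (0.08) were positive where its set test pointed down without passing (adjusted p = 0.811). Called members numbered 2 higher and 1 lower of 17 basement membrane genes (the same over the list alone), 1 higher of 12 smooth muscle genes (the same), 1 lower of 14 endothelial genes (0), 2 lower of 10 principal cell genes (0), 1 higher of 20 polycystic and ciliary genes (0) and 2 higher of 11 immediate early genes (1). The endothelial median was -0.12 but 0.36 when scaled by total counts, and the polycystic and ciliary median was -0.25 but 0.24. The erythrocyte list had 0 of 5 genes called in edgeR, with 4 lower over the list alone, 4 unadjusted and 3 with DESeq2 (adjusted p = 0.506 with an estimated correlation). The adipocyte list had 0 calls, 1 lower gene unadjusted and 0 with DESeq2. The intercalated cell, podocyte and urothelial lists had 0 calls in edgeR, unadjusted and with DESeq2. The podocyte median differed between kidneys, at -1.03, 0.22 and 3.94 in kidneys 1, 2 and 3.

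With the preset correlation 22 of 33 lists passed, against 0 with an estimated correlation and 16 with fry. Those that passed fry included complement (fry adjusted p = 0.00224), macrophages (0.00683) and oxidative phosphorylation (0.0312). Scaling by total counts shifted the median of all genes by 0.48 and gave 4211 higher and 1120 lower genes (79.0% higher in place of 42.3%, and 53.1% with upper quartile factors). Without kidney 1 there were 467 higher and 521 lower genes, with 0 of 55 oxidative phosphorylation, 3 of 25 proximal tubule, 2 of 13 mitochondrially encoded and 4 of 23 matrix calls at medians of -1.38, -3.30, -2.55 and 1.72. Leaving out a single library ended the call of Mep1b, Cyp4a14, Slc12a1, Pvalb, Cd44, Clu, Mmp7, Aqp1, Lrg1 and Sprr1a in at least 1 fit.

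Both cystic region types were also compared gene by gene in their change from non-cystic regions. All 242 genes higher in F4/80-low regions were also higher in F4/80-high regions, where independent lists would share 47.6. Of these, 197 were higher again in F4/80-high than in F4/80-low regions, 43 had no call in that comparison, and Lrg1 and Sprr1a were lower, with no call for either without replicate 2 of F4/80-low kidney 2 (adjusted p = 0.665 and 0.685). Of the 4 genes lower in F4/80-low regions, 3 were lower in F4/80-high regions too, where independent lists would share 0.782, and Slpi was higher. Across the 16034 genes, which are not independent replicates, Pearson's r of both changes was 0.734 and Spearman's rho 0.678. The shared non-cystic libraries give a correlation by themselves: 20 simulations of unchanged groups had a mean r of 0.502 (0.476 to 0.528) and a covariance of 0.125 against 0.866 in the data. With separate non-cystic libraries for each comparison r was 0.526 and 0.626, with 293 and 186 shared higher genes where independent lists would share 52.0 and 32.3. Both sets of non-cystic libraries came from the same 3 kidneys, so what they share by kidney stays in these values. No unchanged groups were simulated for this split.

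**Figure D3:**
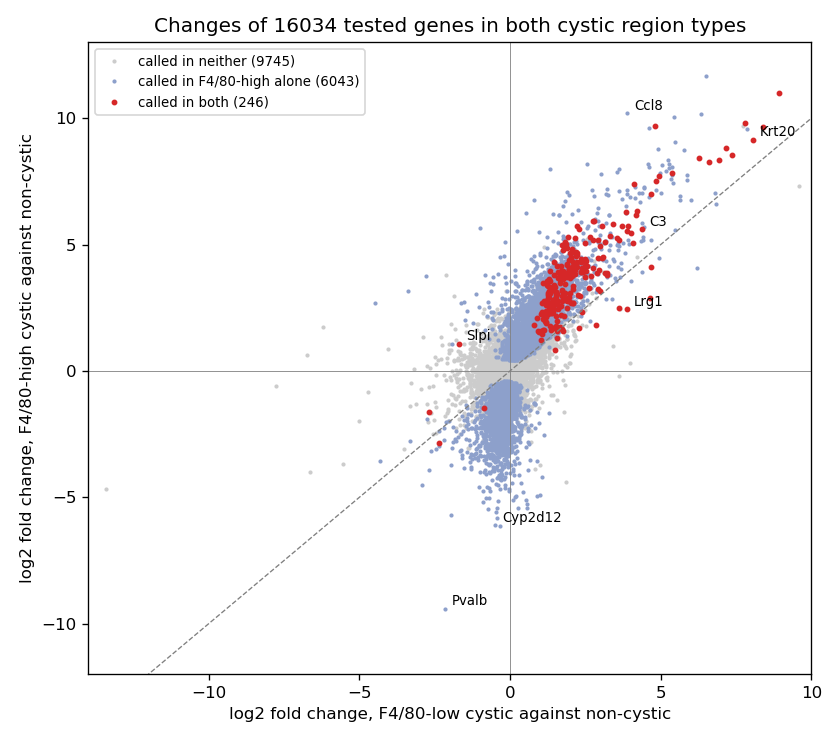
Log2 fold change of each of 16034 genes in F4/80-low (horizontal) and F4/80-high (vertical) cystic regions against non-cystic regions, coloured by calls, with a dashed line where both changes are equal. The 246 genes called in both include Slpi, which alone among them was lower in F4/80-low and higher in F4/80-high regions.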

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

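The tests of a lower share of proximal tubule and of an admixture of F4/80-high tissue were chosen only after the result was seen.

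Replicate 2 of F4/80-low kidney 2 stood far from the other 5 F4/80-low libraries in 5 measures. Spp1 took 8.90% of its counts (0.241 to 2.09% in the others) and Adgre1 reached 14.7 CPM (3.14 to 7.16). Its mean log2 CPM was 8.55 over the proximal tubule list (9.40 to 9.66), 5.67 over the interferon response list (3.22 to 3.68) and 3.72 over the immediate early and heat shock list (2.59 to 2.92). Chance gives such a gap in about 1 in 20 groups, and 14 were found in 132 groups tested, where 6.60 would arise by chance.

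The other 9 of these 14 values stood apart from the other 5 libraries of their region type. In non-cystic kidney 1 replicate 2, Malat1 took 4.26% of counts (5.72 to 6.48% in the others), the distal convoluted and connecting tubule list averaged 5.30 (6.77 to 7.43) and the growth factor list 2.08 (2.36 to 2.53). The monocyte list averaged 1.47 in non-cystic kidney 2 replicate 2 (0.33 to 0.70), and the neutrophil list -1.95 in non-cystic kidney 3 replicate 2 (-0.28 to 0.63). F4/80-low kidney 2 replicate 1 had 9188813 counts in total (7186518 to 7793448). Pkd2 had 81.7 CPM in F4/80-high kidney 1 replicate 1 (54.1 to 58.5). The thick ascending limb list averaged 2.16 in F4/80-high kidney 3 replicate 2 (3.36 to 4.04), and the intercalated cell list 0.59 in F4/80-high kidney 3 replicate 1 (3.51 to 4.43).

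Slpi, Lrg1 and Sprr1a moved differently in the cystic region types, by the test of F4/80-high against F4/80-low. Slpi, a protease inhibitor gene, had a log2 fold change of 2.78 there (adjusted p = 0.00101), being lower in F4/80-low (-1.70) and higher in F4/80-high (1.08) than in non-cystic regions. The Slpi call of 2.78 held in all 34 alternatives. Both calls against non-cystic regions were less stable. The Slpi call in F4/80-low regions was lost in 13 of the 34, among them without F4/80-low kidney 2 replicate 2 and with total counts. The Slpi call in F4/80-high regions was lost in 7, among them without F4/80-high kidney 2 replicate 1 and without the kidney block. Lrg1 had -1.43 (adjusted p = 0.0350) and Sprr1a -1.14 (adjusted p = 0.0180), being more increased in F4/80-low (3.88 and 3.62) than in F4/80-high regions (2.45 and 2.48). Without F4/80-low kidney 2 replicate 2 the Lrg1 value was -0.52 (adjusted p = 0.665) and the Sprr1a value -0.35 (adjusted p = 0.685). With total counts both lost their call as well (Lrg1 -0.91, adjusted p = 0.0564, and Sprr1a -0.61, adjusted p = 0.125). The Lrg1 call was lost in 18 of 34 alternatives. The Sprr1a call was lost with its sign kept in 12, and its sign reversed in others. A different move of Lrg1 and Sprr1a is therefore uncertain.

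Oxidative phosphorylation genes fell in F4/80-high regions, with a median of -1.46 against non-cystic regions. The scaling of the libraries was tested as the cause, and the list's median stayed at -0.86 or below under 3 other scalings, which argues against it. A loss of short abundant transcripts was tested on 77 cytosolic ribosomal protein genes, whose median was 0.14 (quartiles -0.10 and 0.32). They took 1.36 to 1.55% of counts in non-cystic and 2.05 to 2.98% in F4/80-high libraries, so a rise from other cells could hide a loss. They were also less abundant than the oxidative phosphorylation genes (median log2 CPM 7.56 against 8.85). This test therefore cannot decide, and such a loss stays open. A lower share of proximal tubule in the dissected tissue may contribute: the list fell less than the proximal tubule markers in each kidney, by at least 1.40 on the log2 scale. A change within the tubule cells stays open, as does a larger share of nuclear RNA, which was not tested (Malat1 took 4.26 to 6.48% of counts in non-cystic and 6.59 to 9.59% in F4/80-high libraries); the distal convoluted tubule list, which fell by a median of 2.32, is not covered by a loss of proximal tubule alone.

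In 26 of 33 lists the F4/80-low median lay between 0 and the F4/80-high median, both against non-cystic regions; neutrophils (-0.77 and 1.08), thick ascending limb (0.49 and -0.85), Wnt targets (-0.20 and 0.57), polycystic and ciliary genes (0.02 and -0.07), intercalated cells (-1.93 and -1.77), endothelium (0.46 and 0.40) and adipocytes (2.85 and 2.66) did not, nor did Slpi, Lrg1 and Sprr1a. A fixed admixture of F4/80-high tissue could give this, and would bring every list the same share of the way from non-cystic to F4/80-high CPM. Median shares of genes called over 2-fold in F4/80-high regions were 0.094 to 0.184 over the kidneys for macrophages, and 8 of 23 other lists lay apart from that range, where chance gives about 2.3 if lists were independent. MHC class II (0.229 to 0.275), chemokines (0.201 to 0.29) and mitochondrially encoded genes (0.311 to 0.516) lay above it and the injury list met it (0.184 to 0.472). The choice of regions with few macrophages by itself lowers the macrophage share, so this comparison cannot decide. Intercalated cell (0.711 to 1) and distal convoluted and connecting tubule genes (0.409 to 0.993) lay above MHC class II and chemokines, which 1 share for all genes would not give. These 2 lists were picked after their values were seen, and the injury, matrix, complement and proximal tubule ranges overlapped those of MHC class II and chemokines. A milder state of the tissue and an admixture of tissue with fewer macrophages, for which the regions were chosen, stay open.

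Higher calls outnumbered lower calls in F4/80-low regions, 242 to 4. At an unadjusted p below 0.05 the counts were 1499 and 376, and with the DESeq2 Wald test 601 and 74 were called. The size of the excess thus depends on the cut and the test. Scaling was tested as the cause, and the ratio of higher to lower calls was at least 55 under the 3 other scalings, but these moved the median of all genes by only -0.027, -0.002 and 0.12. None could have removed the excess, so these 3 scalings do not decide the question. A scale factor moves all genes alike, and 238 of the 242 higher genes differed by more than 2-fold. The median of all genes was 0.00257, but the normalization itself holds it near 0, so it is no separate evidence. With total counts, which fit no such factor, the median was 0.126 on the log2 scale. A shift of that size would not by itself give those 238 genes, and a larger scale error was not tested. Whether scaling held down the number of lower calls cannot be told here. One library as the cause was tested by 18 fits that each left out 1 library: the ratio was at least 19 in the 15 with lower calls, and the other 3 had none. Higher calls thus outnumbered lower calls whichever library was left out, with 31 and 0 without replicate 2 of F4/80-low kidney 2. With only 0 to 12 lower calls in these fits the ratio could hardly come near 1. The test covers the direction of the excess and cannot decide how much of it came from 1 library. The size of the excess rested on the library with 8.90% Spp1, and a biological difference between the regions, which the design names, stays open as a hypothesis.

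With 3 sums against 3 there are 10 splits of the sums, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many genes: 246 against at most 1 in the other splits for F4/80-low against non-cystic, 6289 against at most 0 for F4/80-high against non-cystic, and 3895 against at most 0 for F4/80-high against F4/80-low. Among the splits that part every kidney, all but the real one gave 0 genes in each comparison, and the split with 1 gene kept both sums of a kidney together.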

How the results depend on the processing

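The list counts without F4/80-low kidney 2 replicate 2, without each kidney and under other scalings were chosen after seeing the data. Over all alternatives fitted to genes, named genes kept direction and side of the threshold in 5387 fits, lost their call in 424, gained one in 30 and reversed in 4, and lists did so in 645, 130, 16 and 1 over the alternatives run for lists (3 scalings, 2 set tests and each kidney left out). For F4/80-low against non-cystic, the 242 higher genes became 500 with no filter, 601 with the DESeq2 Wald test, 570 and 548 with 18 libraries with and without the kidney block, and 33 and 45 with only the libraries of replicate label 1 and 2. The 4 lower genes became 1 with total counts, 23 with no filter, 74 with the Wald test, 31 and 21 with 18 libraries with and without the block, 9 with the kidney as random effect, 28 with only the 2 compared region types, and 0 and 1 with replicate label 1 and 2. For F4/80-high against non-cystic, the 3156 higher genes became 6608 with total counts and 1941 with replicate label 1, and the 3133 lower genes became 1463 and 1766. For F4/80-high against F4/80-low, the 1649 higher genes became 4211 with total counts, 2687 and 2621 with 18 libraries with and without the block, 2904 with the random effect, and 894 and 846 with replicate label 1 and 2. The 2246 lower genes became 1120 with total counts, 1293 with only the 2 compared region types and 1011 with replicate label 1. Fewer libraries lower the depth in the fits by replicate label, and separate libraries count each kidney more often; for the others the cause was not tested. Without the kidney block the 9 sums gave 258 and 4, 3216 and 3139, and 1760 and 2274 higher and lower genes, all within 1.5 times the blocked counts, but 7 of 37, 4 of 73 and 3 of 52 named calls were lost. With the kidney as random effect 22 of 37, 5 of 73 and 8 of 52 were lost, and 101 of the 246 genes called for F4/80-low against non-cystic were shared. Replicate label 1 alone lost 30, 16 and 8 of these named calls, label 2 alone 24, 7 and 10, and leaving out kidney 1 lost 23, 11 and 13, kidney 2 lost 12, 12 and 6, and kidney 3 lost 4, 5 and 5. The correlation of both cystic changes, 0.734, became 0.526 and 0.626 with separate non-cystic libraries, which are fewer per comparison, and the cause was not tested (covariance 0.766 and 0.902, from 0.866).

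Leaving out each kidney gave 22 to 549 higher and 1 to 29 lower genes for F4/80-low against non-cystic, 1737 to 2976 and 1622 to 2881 for F4/80-high against non-cystic, and 467 to 1168 and 521 to 1756 for F4/80-high against F4/80-low, the lowest each time without kidney 1. Leaving out each library gave 31 to 381 and 0 to 12, 2720 to 3327 and 2616 to 3275, and 1096 to 1830 and 1661 to 2441. For F4/80-low against non-cystic the libraries that moved the higher count by more than 1.5 times were replicate 2 of F4/80-low kidney 2 (31), replicate 1 of F4/80-low kidney 3 (76), replicate 1 of non-cystic kidney 2 (129) and replicate 2 of non-cystic kidney 2 (381); for F4/80-high against F4/80-low it was replicate 1 of F4/80-low kidney 2 (1096). Values that reversed were Pkd2 in F4/80-high against non-cystic with total counts (0.031), Sprr1a in F4/80-high against F4/80-low with the random effect (0.10), with replicate label 2 (0.68) and without replicate 1 of F4/80-low kidney 3 (0.01), and the principal cell list in F4/80-low against non-cystic without kidney 3 (0.037). With single kidneys or libraries left out Sprr1a ranged from -1.91 and the principal cell list from -1.02, and the cause was not tested. Of the 99 set tests, 72 passed with the preset correlation and 0 with an estimated correlation. Depth limits the genes with few counts, such as Krt20 with 4 counts in non-cystic regions.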
